A study of Homo sapiens with 92 samples.

How the data were processed

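Raji is an established human Burkitt lymphoma cell line. Raji cells were grown under the skin of immunodeficient NSG mice, and mice with tumours received the MDM2 inhibitor milademetan at 20 mg/kg or vehicle by oral gavage each day for 15 days, with 5 tumours per treatment, per the labels' protocols. Sections of the fixed, paraffin-embedded tumours were profiled with the GeoMx Digital Spatial Profiler. In this assay, probes that carry photocleavable tags bind RNA in a section, light releases the tags from a chosen area, and the tags are sequenced and counted. Regions were divided by antibody staining for the proliferation marker Ki67 and for MYC into 4 segment types, and each collected area of illumination (AOI) was 1 library. The human whole transcriptome panel was used on 4 slides that each held tumours of both treatments. Tumours are named D1 to D5 for milademetan and V1 to V5 for vehicle, as in the labels.

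The authors' deposited gene table holds a count per gene and AOI for 18676 genes, and the count files of the AOIs hold deduplicated counts per probe made with the GeoMx NGS pipeline 3.1.1.6, per the file headers. The submitters' processing notes also name R 4.4.2, edgeR, limma and the build hg38 (GRCh38). No aligner is needed to place reads on a genome in this assay, since tags are matched to the panel's probes. The 18676 genes each matched exactly 1 of the 18815 probes by their counts. The remaining 139 probes matched no gene and were taken as the negative probes, which target no human sequence. In the deposited gene table the lowest value was 1, where the probe files gave 0. This concerned 7.17% of the values. Counts from the probe files were used here, so that 0 stayed 0, and the deposited table was an alternative. Of the 18676 symbols, 18668 were found in the RefSeq gene table of GRCh38.p14 as a symbol or synonym, and gene coordinates come from that table. No pair of AOIs had identical counts.

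The mouse that carried the tumour is the replicate. Counts were therefore summed over the AOIs of each tumour and segment type, which gave 21 libraries with totals from 229014 to 8865880. AOI totals ran from 27398 to 2358166 with a median of 460329.5, and sequencing saturation from 84.9% to 95.7%. Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. For the Ki67+MYC+ segments the model held slide and treatment. Treatment alone was tested in the Ki67-MYC+ segments (3 tumours against 2) and the Ki67-MYC- segments (2 against 2). The difference of the treatment effect between Ki67-MYC+ and Ki67+MYC+ segments was tested as an interaction in the 5 tumours with both. The 4 comparisons between segment types shared 1 fit of all 21 libraries with the tumour as a block. Ki67 and MYC stained the segments, so levels of MKI67 and MYC between segments only check the staining, and segment names give the staining alone. Since edgeR shares information on the spread across genes, standard errors and p-values rest on the spread of all genes together. In the main Ki67+MYC+ treatment test, interaction and segment comparisons, a gene's own spread had no weight. It had little in the Ki67-MYC+ and Ki67-MYC- treatment tests. Small adjusted p-values therefore do not measure how much a gene varied between tumours. For genes past the threshold that are printed with a standard error, the one from the gene's own spread is given as well.

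A gene was over background in a library where its count exceeded the mean plus 2 SD of the log2 negative probe counts, and over background in a comparison where this held in at least 50% of the libraries. The negative probe share of a library is the mean negative probe count as a percentage of the mean gene count. Its difference between treatments, and that of total counts, was tested on tumour means with a two-sided exact permutation test over 252 splits. Values are TMM-scaled CPM (the usual library-size scaled counts), given as mean ± SD over tumours. A gene was marked as resting on 1 AOI where that AOI's CPM exceeded 3 times that of the next highest AOI, with at least 20 counts, which applied to 23 genes.

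There were 34 gene lists, 25 of pathways or cell programs and 9 of markers of other cell types that a xenograft could hold. Host cells are mouse cells and the panel is human, and how far its probes bind mouse RNA was not measured. The marker lists therefore cannot show or exclude host cells. The pathway lists whose results are given were ribosome biogenesis, other MYC-induced genes, MYC-repressed genes, cytosolic ribosomal proteins, translation factors, MYC mRNA-binding proteins, DNA replication and E2F targets, G2/M and mitosis, apoptosis regulators, the unfolded protein and integrated stress response, hypoxia, glycolysis, oxidative phosphorylation, NF-kB targets, interferon response, MHC class I and class II presentation, B cell identity, the germinal center program, plasma cell differentiation, immediate early genes, heat shock, cholesterol synthesis and proteasome subunits. The marker lists covered fibroblasts and matrix, endothelium, macrophages, neutrophils, erythroid cells, skeletal muscle, adipocytes, keratinocytes, and T and NK cells. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were alternatives.

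The groups, designs, gene lists, alternatives other than those named as added and the rule for the genes named were set before the data were examined. The rule names MYC, MDM2, MKI67, MDM4 and CDKN1A whatever their result. Results of 1 other pathway list and of 2 genes that the rule names are left out of the text, while the counts of lists include that list. The rule also names the 10 largest increases and 10 largest decreases among genes past the threshold with an average over 10 CPM and a like direction across tumours. This meant the same direction in every tumour between segments, and between treatments at least 4 of 5 tumours of each treatment on the expected side after removing slide means, or in the smaller comparisons at most 1 tumour out of order. For each list it names up to 4 members past the threshold, or otherwise up to 2 with the smallest p as values, and where fewer than 10 genes passed, the 10 with the smallest p. Genes with near-identical copies, among them SPRR2A, SPRR2B and SPRR2E, CCL4L2, CCL3 and CCL3L3, USP17L17, the KRTAP and OR genes and the HLA genes, are uncertain as to which copy the probe detected.

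Alternatives were RLE size factors, upper quartile scaling, no filter on low counts, only genes over background, DESeq2 1.42.0, leaving out 11 shallow AOIs (under 0.25 of the median total), other block and slide terms, AOIs as libraries in limma voom with the tumour or region as a block, averages of AOI log2 CPM, and leaving out each slide and each tumour. Alternatives added after the data were seen were the deposited table with 0 as 1, the robust quasi-likelihood test, TMM factors from genes over background, leaving out 10 AOIs with a negative probe share over 20%, leaving out the 23 genes that rest on 1 AOI, the negative probe share as a covariate, leaving out the D4 and D5 libraries, further settings for the gene lists, and leaving out each tumour from the depth tests. The tests were checked on simulated counts with 200 changed genes among the real genes. Each simulated gene had the spread shared by genes of its level, and the changed genes averaged over 10 CPM. The check thus did not cover genes with a wider own spread or changed genes with lower counts. With a 2-fold change, edgeR recovered 91.0% of the changed genes in the Ki67+MYC+ treatment comparison, 40.3% in the Ki67-MYC+ and 46.3% in the Ki67-MYC- treatment comparisons. It recovered 14.9% for the interaction, 97.0% for Ki67-MYC+ against Ki67+MYC+ segments, 73.1% for Ki67-MYC- against Ki67+MYC+ and for Ki67+MYC- against Ki67+MYC+ segments, and 74.6% for Ki67-MYC- against Ki67-MYC+ segments.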

Results

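The data addressed how the MDM2 inhibitor milademetan and the staining state of tumour cells related to RNA levels in Raji lymphoma xenografts. There were 48 AOIs from milademetan tumours and 44 from vehicle tumours. Cells positive for both Ki67 and MYC gave 54 AOIs from all 10 tumours, and Ki67-MYC+ cells gave 21 AOIs from 5 tumours. Ki67-MYC- cells gave 10 AOIs from 4 tumours, and Ki67+MYC- cells gave 7 AOIs from 2 tumours. AOIs of a tumour are repeated measures of 1 animal, so the main tests used tumours as replicates. The assay reads RNA, so protein levels and the rate of translation were not measured.

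Counts and background overlapped between treatments in the Ki67+MYC+ segments. Gene counts per AOI, averaged per tumour, were 616300 ± 502900 with milademetan and 761700 ± 255100 with vehicle (n = 5 each, two-sided exact permutation p = 0.54). Negative probes, which show unspecific signal, had 13.72 ± 6.19% of the mean gene count with milademetan and 10.1 ± 1.41% with vehicle (n = 5 each, two-sided exact permutation p = 0.333). An AOI had 7440 ± 1147 genes over background with milademetan and 8381 ± 774.6 with vehicle (n = 5 each, two-sided exact permutation p = 0.159). Among the summed libraries, D4 and D5 had the highest negative probe shares (18.9% and 15.0%), and the other 8 lay between 7.64% and 12.2%. The higher background of D4 and D5 went in the direction in which many gene groups differed between treatments: the median log2 fold change was −0.12 for the 9564 genes over background and 0.25 for the 9103 other genes. The difference of these medians, −0.38, was 0.23 without the D4 and D5 libraries and −0.06 with the negative probe share as a covariate.

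**Figure D1:**
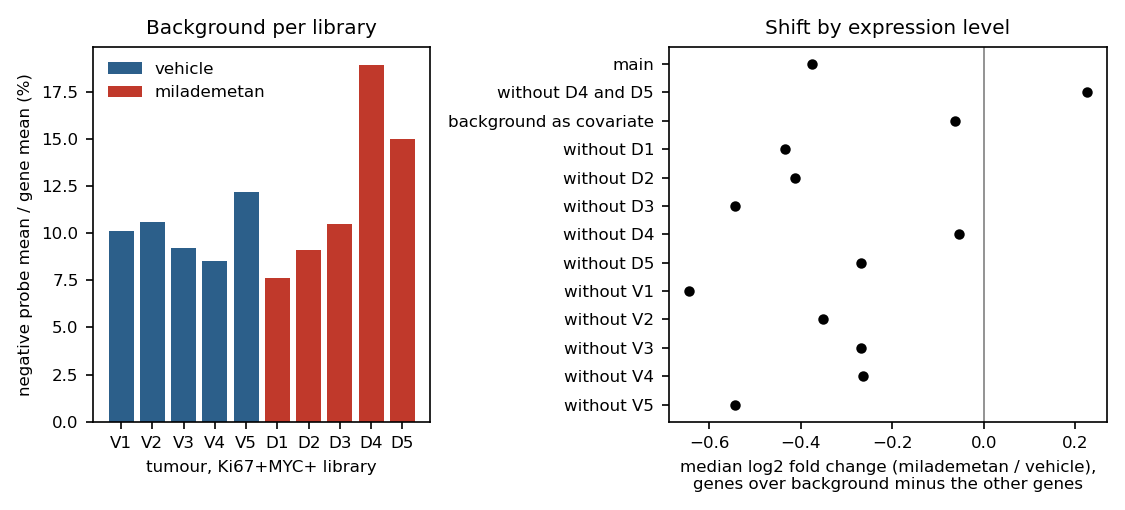
Left: negative probe share (mean negative probe count as a percent of the mean gene count) of each Ki67+MYC+ library, blue for vehicle and red for milademetan; D4 (18.9%) and D5 (15.0%) stand highest. Right: median log2 fold change with milademetan of genes over background minus that of the other genes, with all tumours, without D4 and D5, with the share as a covariate, and with each tumour left out; the difference turns from −0.38 to 0.23 without D4 and D5.

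In Ki67+MYC+ cells, milademetan tumours had more RNA of BMP7, a secreted signal of the TGF-beta superfamily, and of the small proline-rich genes SPRR2A, SPRR2B and SPRR2E, which encode cornified envelope proteins of epithelium. BMP7 was 41.0 ± 22.4 CPM with milademetan and 18.3 ± 9.03 with vehicle (n = 5 each; log2 fold change 1.35 ± 0.183, adjusted p = 3.84e-09). SPRR2A was 40.1 ± 19.8 and 15.8 ± 7.45 CPM (1.32 ± 0.187, adjusted p = 1.38e-08), and SPRR2B (1.18) and SPRR2E (1.17) were higher too, though which of these near-identical copies a probe detected is uncertain. CD59, an inhibitor of complement on the cell surface, rose from 17.8 ± 5.41 to 30.2 ± 6.94 CPM (0.85 ± 0.189, adjusted p = 0.0105), and UBAC2, an endoplasmic reticulum protein, rose by 0.73. The remaining named increases were OTOF (1.41, with 52.6 CPM in D3 and not over background in most libraries), USP17L17 (0.81), DRD5 (0.75) and GRAPL (0.74).

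The decreases in Ki67+MYC+ cells included a cytokine receptor and a chemokine. IL1R2, a decoy receptor for interleukin 1, was 28.5 ± 18.3 CPM with milademetan and 52.5 ± 15.6 with vehicle (−1.18 ± 0.192, adjusted p = 3.14e-06). CCL22, a chemokine and NF-kB target, was 77.5 ± 44.0 and 153.5 ± 52.95 CPM (−1.16 ± 0.214, adjusted p = 0.000159). CHI3L2, a chitinase-like protein, fell from 191.6 ± 29.1 to 108.1 ± 62.0 CPM (−1.02, adjusted p = 0.0107), and MPEG1, a pore-forming protein of phagocytes and B cells (−0.88), and TNFRSF14, a receptor that regulates lymphocytes (−0.81), fell with adjusted p = 0.0256 each. D2 lay nearer the vehicle mean for all 15 named genes. The other 4 milademetan tumours lay nearer the milademetan mean for 13 to 15 of them. Within slides S1 to S4, log2 differences were 1.08, 1.07, 1.65 and 1.27 for BMP7, 1.68, 0.71, 1.14 and 1.69 for SPRR2A, and 0.70, 0.17, 0.97 and 1.24 for CD59. They were −1.20, −2.05, −1.11 and −0.54 for IL1R2, and −0.84, −1.56, −1.46 and −0.75 for CCL22.

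**Figure D2:**
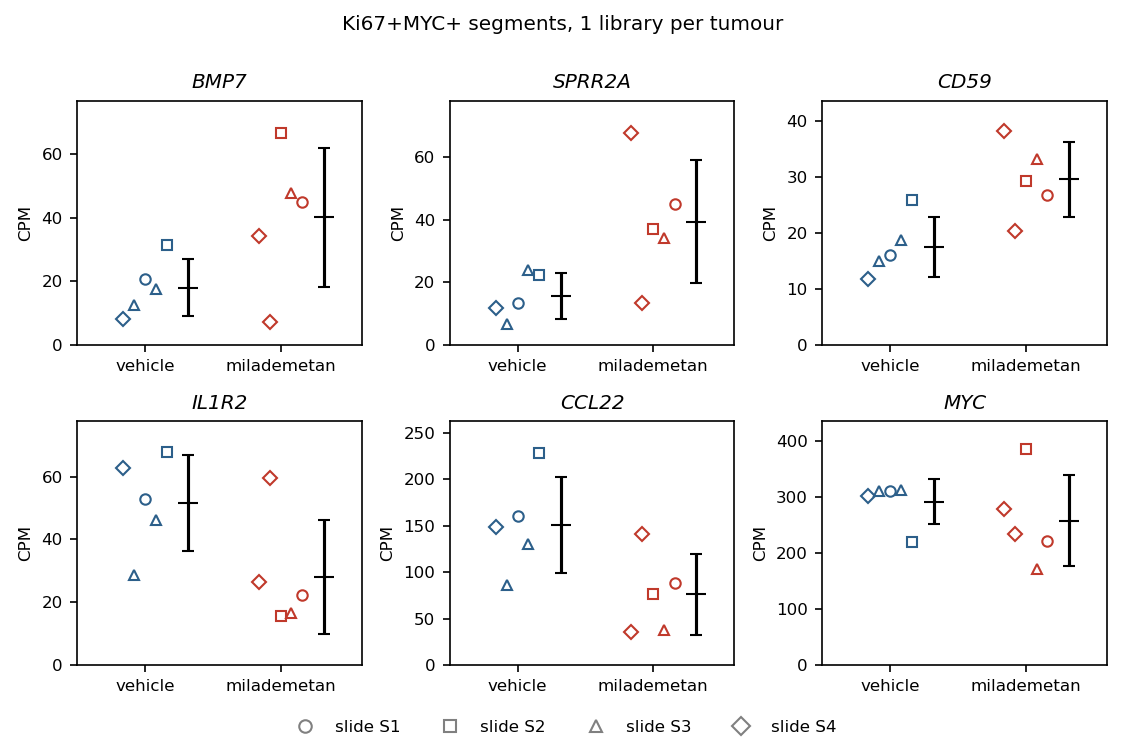
RNA level (CPM) per tumour in Ki67+MYC+ segments for BMP7, SPRR2A, CD59, IL1R2, CCL22 and MYC, blue for vehicle and red for milademetan; marker shapes show the slide and bars the mean ± SD of 5 tumours. Means of BMP7, SPRR2A and CD59 were higher and those of IL1R2 and CCL22 lower with milademetan, with D2 nearer the vehicle mean for these 5 genes, and the MYC values of the treatments overlapped.

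MYC RNA in Ki67+MYC+ cells was 262.3 ± 80.8 CPM with milademetan and 295.7 ± 41.0 with vehicle, a difference that did not pass the test (n = 5 each; −0.23 ± 0.233, adjusted p = 0.702). Its log2 differences within slides S1 to S4 were −0.48, 0.81, −0.83 and −0.25. MDM2, the drug's target, was 32.6 ± 5.34 and 31.6 ± 5.73 CPM (0.03 ± 0.185, adjusted p = 0.95). CDKN1A, which encodes a cell cycle inhibitor, was 46.1 ± 13.9 and 54.0 ± 13.3 CPM (−0.35 ± 0.192, adjusted p = 0.52). MKI67, which encodes Ki67, had a log2 fold change of −0.33 ± 0.233 (adjusted p = 0.608). MDM4, an MDM2 homolog, did not pass either (−0.12, adjusted p = 0.816). On GRCh38.p14, MYC lies on chromosome 8 at 127735434 to 127742951 and MDM2 on chromosome 12 at 68808172 to 68850686.

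Gene groups of growth and protein synthesis had lower medians with milademetan in Ki67+MYC+ cells, in the direction of the background difference, and for many lists this direction turned without D4 and D5. All 32 ribosome biogenesis genes had negative log2 fold changes (median −0.28, camera adjusted p = 3.87e-09), as did 77 of 78 cytosolic ribosomal proteins (−0.30, 1.75e-18), 28 of 30 other MYC-induced genes (−0.25, 4.81e-06) and 36 of 40 translation factors (−0.23, 3.96e-07). These 4 lists had adjusted p = 0.399 with an estimated correlation. Lower medians were also found for oxidative phosphorylation (−0.29, adjusted p = 9.59e-11), glycolysis (−0.29, 7.22e-06), proteasome subunits (−0.28, 3.42e-07), MYC mRNA-binding proteins (−0.27, 0.000127), cholesterol synthesis (−0.23, 1.37e-05) and the unfolded protein and integrated stress response (−0.22, 0.000848). The same held for G2/M and mitosis (−0.18, adjusted p = 3.46e-05), DNA replication and E2F targets (−0.17, 5.52e-05) and apoptosis regulators (−0.15, 0.0068). With an estimated correlation these 9 lists had adjusted p from 0.399 to 0.474.

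Without D4 and D5 the direction turned for 19 of the 26 lists past the threshold, and 6 passed as higher with milademetan: G2/M (camera adjusted p = 0.000158), oxidative phosphorylation (0.000357), proteasome subunits (0.000357), translation factors (0.000903), E2F targets (0.00105) and other MYC-induced genes (0.00187). Ribosome biogenesis turned without passing (0.0914), and hypoxia (0.00197) and immediate early genes (0.000604) still passed as lower. On slides S2 and S4, which then alone held both treatments, the milademetan libraries had lower negative probe shares than the vehicle libraries. The turn to higher thus lies in the direction of this background difference, and does not show that these lists rose with milademetan. Among genes over background 13 of the 22 lists that could be tested passed as before, and those that did not included E2F targets (0.276), G2/M (0.151), apoptosis regulators (0.671) and the stress response (0.176).

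Lymphocyte and signal groups had lower medians too: MHC class I presentation (median −0.40, 12 of 12 negative, camera adjusted p = 3.96e-07), B cell identity (−0.30, 3.39e-06), hypoxia response (−0.25, 0.00016), germinal center program (−0.22, 0.00241), NF-kB targets (−0.20, 0.000192), MHC class II presentation (−0.19, 0.0209), immediate early genes (−0.15, 0.000714) and plasma cell differentiation (−0.15, 0.0262). Among genes over background, NF-kB targets (0.175), MHC class II (0.671), the germinal center program (0.193) and plasma cell differentiation (0.151) did not pass, and MHC class II turned without D4 (0.971). With an estimated correlation the lowest adjusted p among all 34 lists was 0.303, for hypoxia. Markers of other cell types that had no member over background had higher medians: endothelium (0.46, adjusted p = 0.000714), neutrophils (0.34, 0.00775), T and NK cells (0.29, 0.0264) and keratinocytes (0.22, 0.0336), each with adjusted p = 0.399 with an estimated correlation. Lists that did not pass were interferon response (0.11, adjusted p = 0.0894), MYC-repressed genes (median 0.06, with a test direction of lower, 0.667), heat shock (−0.11, 0.111), fibroblasts and matrix (0.15, 0.348), macrophages (0.33, 0.0739), erythroid cells (0.11, 0.473), skeletal muscle (0.17, 0.213) and adipocytes (0.14, 0.537). CCL22 was the 1 list member past the threshold over all genes. Adjusted over the list alone, 4 hypoxia genes, 3 immediate early genes, 2 MHC class I genes, and 1 each of the other MYC-induced, stress response, NF-kB and B cell lists were lower, and 1 each of the interferon, neutrophil, keratinocyte, and T and NK cell lists were higher.

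Of 18667 genes tested with edgeR between treatments in Ki67+MYC+ cells, 25 passed an adjusted p of 0.05, 16 higher and 9 lower with milademetan, and 20 of the 25 were over background. With RLE size factors 10 passed (8 higher, 2 lower), and the balance was the opposite with AOIs as libraries (15 higher, 122 lower), all segments in limma voom (29 and 142) and averages of AOI log2 CPM (4 and 14). None passed with DESeq2 (1192 at an unadjusted p under 0.05), among genes over background only (1004 in edgeR), with the negative probe share as a covariate (1229) or without D4 and D5 (1190), against 1872 in edgeR with all genes. The count was 9 without D1, 65 without D2, 102 without D3, 11 without D4, 9 without D5, 205 without V1, 8 without V2, 9 without V3, 14 without V4 and 102 without V5. Across 32 alternatives DRD5 passed in 9, UBAC2 in 10, GRAPL in 11, MPEG1 and USP17L17 in 12 each, TNFRSF14 in 13, CD59 in 16 and CHI3L2 in 17. The own spread of the 15 named genes was 1.74 to 11 times (median 4.09) the shared spread, so that standard errors from own spread would be 0.445 for BMP7, 0.62 for SPRR2A, 0.39 for IL1R2, 0.468 for CCL22 and 0.28 for CD59. The median log2 fold change of all genes was 0.05, and 0.16 with upper quartile scaling or 0.20 with TMM factors from genes over background. List medians are given without subtracting this value, while camera tests a list against the other genes.

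In Ki67-MYC+ cells, SPARC, TGFBI, CFB and BARX2 were lower and SPRR2B higher with milademetan. SPARC, a matrix glycoprotein, was 61.3 ± 6.30 CPM with milademetan (n = 3) and 250.6 ± 255 with vehicle (n = 2; −1.96 ± 0.337, edgeR adjusted p = 0.00503). TGFBI, a matrix protein induced by TGF-beta, was 14.8 ± 2.92 and 55.1 ± 35.8 CPM (−1.65, adjusted p = 0.0106). CFB, complement factor B, was 22.3 ± 1.92 and 51.1 ± 0.75 CPM (−1.19, adjusted p = 0.0489), and BARX2, a homeobox factor not over background, had −1.61 (adjusted p = 0.0223). SPRR2B was higher, with 35.6 ± 20.9 against 8.06 ± 2.81 CPM (1.88, adjusted p = 0.0315). Within slides S1 and S3, the slides that held both treatments, log2 differences were −0.09 and −2.97 for SPARC, −1.15 and −2.50 for TGFBI, −1.08 and −1.32 for CFB, −1.37 and −0.50 for BARX2, and 2.31 and 2.54 for SPRR2B. MYC was 266.6 ± 39.8 CPM with milademetan and 353.4 ± 14.9 with vehicle (−0.41 ± 0.258, adjusted p = 0.999), and −0.37 and −0.21 within the slides. MDM2 (−0.04), MKI67 (−0.10), MDM4 (0.55) and CDKN1A (0.17) had adjusted p = 0.999 each.

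Growth groups had lower medians in Ki67-MYC+ cells with milademetan, where the background shift had the same direction (median −0.06 for genes over background and 0.18 for the others). Negative probe shares were 8.67%, 9.55% and 12.4% in D2, D4 and D5, and 9.20% and 8.38% in V2 and V3. The lists were ribosome biogenesis (−0.30, 31 of 32 negative, camera adjusted p = 2.74e-06), other MYC-induced genes (−0.30, 9.6e-06), oxidative phosphorylation (−0.26, 1.34e-06), E2F targets (−0.24, 9.56e-06), proteasome subunits (−0.23, 1.65e-05), G2/M (−0.21, 1.65e-05), translation factors (−0.20, 0.00011), MYC mRNA-binding proteins (−0.19, 0.00594) and ribosomal proteins (−0.14, 0.000282). The interferon response list had a higher median (0.38, 26 of 28 positive, adjusted p = 0.000108), but it did not pass without D2 and turned to lower without V2 (adjusted p = 0.584). The lowest adjusted p of the 34 lists with an estimated correlation was 0.878, and all 10 lists passed in the same direction among genes over background. Without D5, the library with the highest negative probe share here, 4 of the 10 passed in camera. Without AOIs of high background 8 of the 10 passed in the same direction, and 0 had the opposite direction. SPARC was the 1 list member past the threshold over all genes, in the fibroblast and matrix list (median 0.05, adjusted p = 0.385). Adjusted over the list alone 4 members of that list and 1 macrophage marker were lower, and 2 stress response genes and 1 germinal center gene were higher. Of 15487 genes tested, 1 was higher and 4 were lower. The balance depended on the model: with a slide term, in which D2 was the 1 library of its slide, 35 were higher and 18 lower, among them 4 of the 5. With RLE size factors 5 were higher and 5 lower, and none passed with DESeq2 (161 at an unadjusted p under 0.05), upper quartile scaling (579 in edgeR), genes over background only (327) or without D5 (583), against 563 in edgeR with TMM. The count was 12 without D2 (11 higher), 11 without D4 (6 higher), 5 without V2 (3 higher) and 41 without V3 (14 higher), and the own spread of the named genes was 0.11 to 14.2 times the shared spread (standard error from own spread 1.27 for SPARC). Across 17 or 18 alternatives CFB passed in 5, BARX2 and SPARC in 7 each, TGFBI in 8 and SPRR2B in 10.

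The interferon response had the smallest camera adjusted p of the lists between treatments in Ki67-MYC- cells, with 2 tumours per treatment. Of 24 genes tested, 15 rose with milademetan and all 24 log2 fold changes were positive (median 1.07, camera adjusted p = 2.67e-18), with 20 higher adjusted over the list alone. With an estimated correlation the list had an adjusted p = 0.817. IRF7, a transcription factor that drives type I interferon, was 123.7 ± 38.3 CPM with milademetan and 38.6 ± 5.31 with vehicle (n = 2 each; 1.52 ± 0.272, edgeR adjusted p = 4.77e-05). IFI44L was 265.9 ± 75.6 and 99.5 ± 27.6 CPM (1.32 ± 0.236, adjusted p = 4.77e-05), IFI44 155.3 ± 75.2 and 47.8 ± 3.92 (1.47, adjusted p = 4.77e-05), and IFITM1, which restricts virus entry, 314.0 ± 114 and 126.9 ± 62.3 (1.20, adjusted p = 0.000276). The antiviral genes MX2 (2.15 ± 0.543) and OASL (1.69 ± 0.425) rose too. Standard errors from own spread would be 0.364 for IRF7, 0.41 for IFI44L, 0.947 for MX2 and 0.459 for OASL. On slide S1, the slide that held both treatments, the log2 differences of D5 from V3 were 1.81 for IRF7, 1.42 for IFI44L, 2.02 for IFI44, 1.20 for IFITM1, 2.78 for MX2 and 1.76 for OASL. This D5 library summed 2 AOIs and had 229014 counts, the lowest total of all libraries. Interferon response genes also varied widely between tumours in Ki67+MYC+ cells, as given below. With 2 tumours per treatment, such variation cannot be told apart from an effect of milademetan.

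Chemokines and single B cell genes also differed between treatments in Ki67-MYC- cells. The chemokines CCL4L2 (414.8 ± 204 against 61.9 ± 5.31 CPM; 2.63 ± 0.251, edgeR adjusted p = 1.05e-19) and CCL3 (310 ± 63.3 against 125.3 ± 4.58 CPM; 1.25, adjusted p = 8.8e-05) rose, and which of their near-identical copies the probes detected is uncertain. KLHL6, a B cell receptor signalling gene, rose from 55.1 ± 6.36 to 185.9 ± 25.7 CPM (1.70), and SERPINA9, a germinal center serpin, from 104.6 ± 16.5 to 292.2 ± 44.6 CPM (1.44). NR4A1, an immediate early receptor (2.10), GPR18 (1.91), SPRR2A (1.92), SPRR2B (1.74), SPRR2E (1.65), LPIN1 (1.58) and the matrix gene FN1 (1.16) were higher too. IL1R2 fell from 70.1 ± 16.0 to 22.03 ± 0.213 CPM (−1.66 ± 0.329, adjusted p = 0.000341), and CCL22 had −0.89. HSPA6, an inducible heat shock protein (−1.44), ENO1, a glycolytic enzyme (918.7 ± 264 against 1633 ± 87.2 CPM; −0.80), and the stress genes DDIT4 (−1.03) and SLC7A5 (−0.81) fell, as did BACE2 (−1.53), KRTAP5-8 (−1.46), UBE2E3 (−1.43), KPNA6 (−1.43), MNAT1 (−1.41) and SPARCL1 (−1.37). Standard errors from own spread would be 0.621 for CCL4L2 and 0.298 for IL1R2. On slide S1 the log2 differences were 3.07 for CCL4L2, 1.46 for CCL3, 1.99 for KLHL6, 1.79 for SERPINA9, 2.58 for NR4A1, 2.81 for SPRR2A and −1.37 for IL1R2. TNR (−3.54, from 1 AOI) and ACTA1 (−1.83) were not over background.

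**Figure D3:**
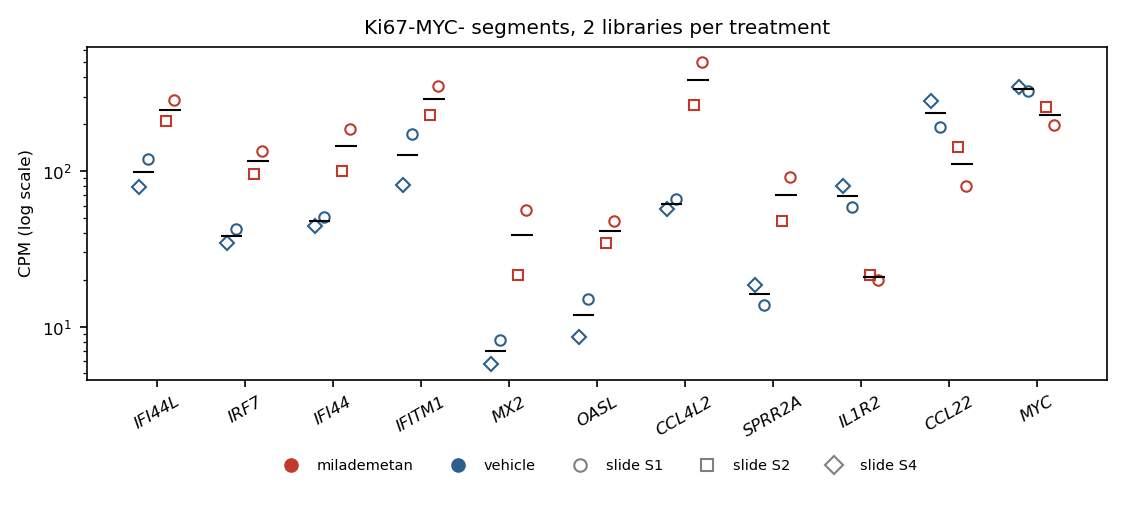
RNA level (CPM, log axis) in the 2 milademetan (red) and 2 vehicle (blue) libraries of Ki67-MYC- segments for interferon response genes, chemokines, SPRR2A, IL1R2 and MYC; marker shapes show the slide and black lines the mean. IRF7 had means of 123.7 with milademetan and 38.6 with vehicle in the fit of these libraries, and IL1R2 22.03 and 70.1.

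Other lists in Ki67-MYC- cells with a camera adjusted p under 0.05 were E2F targets (median −0.35, 33 of 40 negative, 0.000111), other MYC-induced genes (−0.14, 0.0448) and oxidative phosphorylation (−0.13, 0.0448, although its member NDUFS5 rose), each with adjusted p = 0.817 with an estimated correlation. Among genes over background, other MYC-induced genes and oxidative phosphorylation had adjusted p = 0.0634 each. Members past the threshold were 2 lower in the stress response list, 1 lower each in hypoxia, glycolysis, heat shock and proteasome (PSMD3, −0.95), 1 higher (CCL3) and 2 lower (CCL22 and EBI3) in NF-kB targets, 1 higher (SPIB, 0.79) and 2 lower (BANK1, −1.04, and CR2, −0.85) in B cell identity, and 1 higher each in the germinal center, immediate early and fibroblast lists. Adjusted over the list alone these were the same counts except 2 lower in hypoxia, 2 lower in glycolysis, 1 higher and 1 lower in oxidative phosphorylation, and 2 higher and 4 lower in B cell identity, with 2 lower in MHC class I, 1 higher in MHC class II, 1 lower in plasma cell differentiation and 1 lower in MYC-repressed genes besides. MYC was 240.8 ± 26.9 CPM with milademetan and 339.4 ± 19.6 with vehicle (−0.46 ± 0.221, edgeR adjusted p = 0.468; −0.55 on slide S1). MDM2 was 39.6 ± 0.51 and 26.5 ± 10.8 CPM (0.56, adjusted p = 0.657), and CDKN1A (0.40), MKI67 (−0.27) and MDM4 (−0.05) did not pass. Of 9758 genes tested in 2 against 2 tumours, 54 were higher and 42 lower, and 94 of the 96 were over background. With DESeq2 10 were higher and 5 lower. The count was 49 without D5, 46 without V3 (22 higher, 24 lower), 14 without V1 and 149 without D3 (47 higher, 102 lower), and without V1 the 6 interferon genes named no longer passed. Across 15 or 16 alternatives ACTA1 and EBI3 passed in 7 each, and CCL22, CR2, MNAT1, SPIB and UBE2E3 in 8 each. The own spread of the 37 named genes, which rests on 2 residual degrees of freedom, was 0.0596 to 32.9 times (median 1.84) the shared spread.

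Ki67+MYC- cells came from 1 tumour per treatment, so no test was made. In D3 and V5, MYC was 241.9 and 207.8 CPM, MDM2 38.6 and 33.7, CDKN1A 51.7 and 68.1, BMP7 41.4 and 23.1, IL1R2 24.5 and 87.7, CCL22 67.8 and 221.1, and IFITM1 58.4 and 115.8.

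The treatment difference itself differed between Ki67-MYC+ and Ki67+MYC+ cells for 3 genes. CFB had a log2 ratio of Ki67-MYC+ to Ki67+MYC+ cells of −0.08 ± 0.91 in milademetan tumours (n = 3) and 1.27 ± 0.24 in vehicle tumours (n = 2; difference −1.58 ± 0.314, edgeR adjusted p = 0.00455). BARX2 (−1.87 ± 0.364, adjusted p = 0.00455) and FAM9C (3.12 ± 0.673, adjusted p = 0.0219) were not over background. MYC had a difference of 0.15 ± 0.362, MDM2 of 0.23, MKI67 of 0.40, CDKN1A of 0.39 and MDM4 of 0.81 ± 0.318, with adjusted p = 1 each. No list passed in camera, with the lowest adjusted p for hypoxia and glycolysis (0.069 each), and 3 hypoxia genes were higher adjusted over the list alone. With upper quartile scaling 1 gene was higher and 5 were lower among 6 past the threshold, and with DESeq2 none passed (50 at an unadjusted p under 0.05, against 399 in edgeR). The count was 2 without D2, 2 without D5, 2 without V3, 1 without V2 and 16 without D4, and the own spread of the 3 genes was 3.58 to 5.29 times the shared spread (standard error from own spread 0.594 for CFB, 0.689 for BARX2 and 1.55 for FAM9C).

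Energy, protein synthesis and protein turnover groups had higher medians in Ki67-MYC+ than in Ki67+MYC+ cells of the same tumours, in the direction of a background difference. The Ki67-MYC+ library had the lower negative probe share in 5 of 5 tumours: 8.67% against 9.09% in D2, 9.55% against 18.9% in D4, 12.4% against 15.0% in D5, 9.20% against 10.6% in V2 and 8.38% against 9.21% in V3. Of the 19 lists past the threshold 10 passed without D4 and 8 without AOIs of high background, where G2/M turned to lower. All 60 oxidative phosphorylation genes had positive log2 ratios (median 0.29, camera adjusted p = 3.59e-18), and 22 were higher adjusted over the list alone. For this and every other list the adjusted p with an estimated correlation was 0.406 or more. The same direction held for all 31 proteasome subunits (0.29, 8.79e-12; 9 higher adjusted over the list alone), 77 of 78 ribosomal proteins (0.27, 7.29e-25), 39 of 40 translation factors (0.29, 1.21e-13), other MYC-induced genes (0.29, 7.93e-09), ribosome biogenesis (0.23, 2.68e-08) and MYC mRNA-binding proteins (0.27, 8.96e-07). Antigen presentation and B cell groups followed: MHC class II (0.25, 0.000222; 5 higher adjusted over the list alone), MHC class I (0.25, 0.000694), NF-kB targets (0.26, 1.68e-05), B cell identity (0.21, 0.000198) and plasma cell differentiation (0.18, 0.0402). Cholesterol synthesis (0.21, 7.37e-05), glycolysis (0.25, 0.00535), the stress response (0.20, 0.00212), E2F targets (0.19, 0.000235), G2/M (0.14, 0.00319) and apoptosis regulators (0.12, 0.0258) had higher medians too, and endothelial markers, none over background, a lower median (−0.31, 0.0481). Among genes over background, whose median was 0.13, G2/M turned to lower (adjusted p = 0.891), and E2F targets (0.618), apoptosis regulators (0.802), the stress response (0.485), plasma cell differentiation (0.306) and cholesterol synthesis (0.0543) did not pass.

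No list member passed over all genes between Ki67-MYC+ and Ki67+MYC+ cells. Adjusted over the list alone, 7 glycolysis genes were higher and 2 lower, 4 heat shock genes higher and 3 lower, and 3 cholesterol, 1 NF-kB and 1 plasma cell genes higher. Lower were 2 hypoxia genes, 2 neutrophil markers, and 1 marker each of endothelium, macrophages and keratinocytes. Genes that fell in 5 of 5 tumours were SPATA2L (24.99 ± 7.48 against 44.0 ± 20.0 CPM; −0.74 ± 0.144, or ± 0.152 from own spread, edgeR adjusted p = 0.00124), MST1, which encodes macrophage-stimulating protein (12.9 ± 3.45 against 21.4 ± 4.13 CPM; −0.77, adjusted p = 0.0202), and PRKAB2, a subunit of the energy sensor AMPK (14.8 ± 3.00 against 24.9 ± 5.40 CPM; −0.69, adjusted p = 0.0348). FOXD4L5 (−0.71), KRTAP10-2 (−0.74), OR4F4 (−0.72), SPDYE3 (−0.69), CYSRT1 (−0.65), UNC5A (−0.62) and OR7C1 (−0.88) were lower, and HCRTR2 (0.99), not over background, was higher. The decreases lie in the direction of the lower negative probe share of the Ki67-MYC+ library in 5 of 5 tumours. Genes not over background had a median of −0.22. A difference in background therefore cannot be told apart from a change of these genes. MKI67 RNA did not differ past the threshold in Ki67-MYC+ cells, which were chosen as negative for Ki67 (0.08, edgeR adjusted p = 0.786, and −0.234 to 0.144 across alternatives). Its log2 ratio was 0.793 in D4 and −0.196 to 0.0198 in the other tumours. The G2/M and E2F lists had higher medians, but among genes over background G2/M turned to lower and E2F targets did not pass. The RNA thus gave no clear support for the Ki67 staining and no evidence against it. MYC, stained in both, had 0.31 ± 0.135 (adjusted p = 0.277). CDKN1A had 0.18, MDM4 0.10 and MDM2 0.02. Of 18675 genes tested, 3 were higher and 22 lower, and 15 of the 25 were over background. More genes were higher than lower with AOIs as libraries and regions as blocks (51 higher, 28 lower), without AOIs of high background (3 and 1) and without D4 (3 and 2). The fit with regions as blocks took regions of 1 tumour as separate replicates. None passed with DESeq2 (1874 at an unadjusted p under 0.05, against 2801 in edgeR), and the count was 5 without D4, 5 without V3, 11 without V2, 70 without D2 and 35 among only the tumours and segments compared. The median of genes over background was 0.13 and of the others −0.22, and that of all genes moved from −0.03 to −0.14 with upper quartile scaling and −0.18 with TMM factors from genes over background.

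Antigen presentation rose in Ki67-MYC- cells compared with Ki67+MYC+ cells of the same tumours. Of 12 MHC class II genes, 7 passed (10 adjusted over the list alone; median 0.58, camera adjusted p = 9.39e-10), and of 12 MHC class I genes, 5 passed (11 adjusted over the list alone; 0.45, 3.83e-08), each higher. Both lists had adjusted p = 0.501 with an estimated correlation. HLA-DRB1, an MHC class II chain, was 1706 ± 229 CPM in Ki67-MYC- cells and 1054 ± 180 in Ki67+MYC+ cells (n = 4 tumours; 0.68 ± 0.146, or ± 0.15 from own spread, edgeR adjusted p = 0.00302). HLA-DPA1 (0.66), HLA-DRA (0.62) and HLA-DMA (0.64) rose as well. B2M, the light chain of MHC class I, was 4567 ± 791 and 3015 ± 853 CPM (0.64, adjusted p = 0.00901), and TAP1, the peptide transporter, 271.3 ± 78.1 and 155.3 ± 37.3 (0.78 ± 0.15, or ± 0.23 from own spread, adjusted p = 0.000422), with HLA-B (0.59). All 7 genes were higher in 4 of 4 tumours, but they no longer passed in edgeR without D3, without D5 or, except TAP1, without V3.

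Interferon response genes were higher in the Ki67-MYC- cells of 3 of 4 tumours. Of 28 genes, 10 passed (17 adjusted over the list alone; median 0.48, camera adjusted p = 4.09e-09), with adjusted p = 0.501 with an estimated correlation. IFI27 was 405.4 ± 210 CPM in Ki67-MYC- cells and 134.3 ± 31.8 in Ki67+MYC+ cells (n = 4 tumours; 1.34 ± 0.153, edgeR adjusted p = 2.1e-14), IFI6 436.1 ± 167 and 162.5 ± 60.7 (1.26 ± 0.153), IFITM1 209.6 ± 115 and 80.8 ± 17.9 (1.17), and IFI44 had 0.85. Standard errors from own spread would be 0.453 for IFI27 and 0.406 for IFI6. With the robust test of edgeR, which lets genes with a wide spread keep it, these 4 genes had adjusted p from 0.277 to 0.483.

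Of 29 genes of the unfolded protein and integrated stress response, 5 rose in Ki67-MYC- cells (10 higher and 1 lower adjusted over the list alone; median 0.15, camera adjusted p = 0.000806, and 0.501 as adjusted p with an estimated correlation). HSPA5, a chaperone of the endoplasmic reticulum, was 286.0 ± 15.5 CPM against 177.0 ± 36.1 (0.71 ± 0.15, or ± 0.184 from own spread, edgeR adjusted p = 0.00225), with MANF (0.64), CALR (0.63) and PDIA6 (0.56). DNAJB1, a heat shock cochaperone of the cytosol, fell in 4 of 4 tumours from 97.3 ± 34.4 to 40.8 ± 18.0 CPM (−1.09 ± 0.183, or ± 0.295 from own spread, adjusted p = 8.32e-06). The heat shock list did not pass (median 0.31, adjusted p = 0.241), with 6 members higher and 3 lower adjusted over the list alone. Of 19 NF-kB targets, 2 rose, CD83 (0.68) and CCL22 (0.60), and 9 did so adjusted over the list alone (median 0.23, adjusted p = 4.01e-05, and 0.501 as adjusted p with an estimated correlation). CD59 (47.7 ± 29.5 against 20.96 ± 8.36 CPM; 0.98), LGALS3BP, a secreted glycoprotein (239 ± 81.8 against 122.8 ± 11.4 CPM; 0.86), CTSS, a protease of antigen processing (206.9 ± 34.5 against 124.5 ± 23.5 CPM; 0.74), PLSCR1 (0.76), MPEG1 (0.74), GPKOW (0.89), CD99L2 (0.83) and the transferrin receptor TFRC (0.65) were higher, TFRC as the 1 member of the other MYC-induced list past the threshold (1 higher and 1 lower adjusted over the list alone). IGFBP7, a secreted matrix protein (16.5 ± 6.45 against 37.0 ± 9.49 CPM; −1.06), FAM102A (−0.87), RBMS2 (−1.13) and PTBP1, a splicing and MYC mRNA-binding protein (2601 ± 449 against 3771 ± 940 CPM; −0.60), were lower, as were EML6 (−1.68, from 1 AOI), RASIP1 (−1.46) and ATP6AP1L (−1.36), which were not over background. Across 22 to 24 alternatives, GPKOW passed in 8, ATP6AP1L in 10, CD99L2 in 11, PLSCR1 in 12, CCL22, RASIP1 and RBMS2 in 14 each, PTBP1 in 15, and IFI44 and PDIA6 in 16 each. Adjusted over the list alone, 1 gene each of the MYC-repressed, G2/M, glycolysis and proteasome lists was higher, and 1 each of the MYC mRNA-binding and fibroblast lists was lower.

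**Figure D4:**
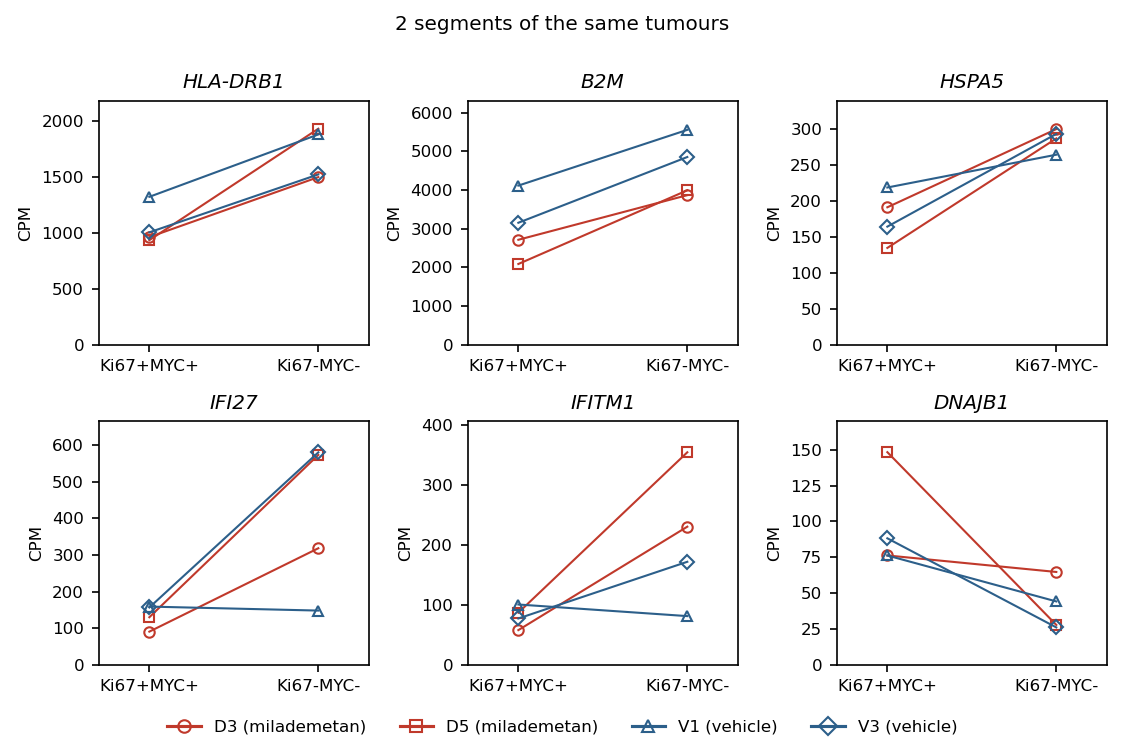
RNA level (CPM) in Ki67+MYC+ and Ki67-MYC- segments of the same tumour for HLA-DRB1, B2M, HSPA5, IFI27, IFITM1 and DNAJB1; each line is 1 of the 4 tumours with both segments, blue for vehicle and red for milademetan, with a marker per tumour. HLA-DRB1, B2M and HSPA5 were higher and DNAJB1 lower in Ki67-MYC- segments of 4 of 4 tumours, and IFI27 and IFITM1 were higher in 3 of 4.

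Other groups with higher medians in Ki67-MYC- than Ki67+MYC+ cells were proteasome subunits (0.29), G2/M (0.21) and oxidative phosphorylation (0.20), with camera adjusted p = 4.09e-09 each, B cell identity (0.26, 2.17e-06; 5 higher adjusted over the list alone), translation factors (0.16, 5.46e-07), other MYC-induced genes (0.16, 0.000168), ribosomal proteins (0.09, 0.000133), ribosome biogenesis (0.13, 0.00041), cholesterol synthesis (0.17, 0.000772), E2F targets (0.10, 0.00483), MYC mRNA-binding proteins (0.13, 0.0102) and plasma cell differentiation (0.24, 0.0336; 3 higher adjusted over the list alone). Keratinocyte markers, none over background, were lower (−0.41, adjusted p = 0.0438). The Ki67-MYC- library had the lower negative probe share in D3, D5 and V3 and the higher one in V1. Genes over background had a median of 0.09 and the others −0.17, and among genes over background ribosomal proteins turned to lower (0.693), while ribosome biogenesis (0.357), MYC mRNA-binding proteins (0.357), E2F targets (0.884) and cholesterol synthesis (0.137) did not pass. With an estimated correlation the lowest adjusted p of all lists was 0.501. RNA gave no support for the staining here either: MKI67 was above 0 in every alternative (0.27, edgeR adjusted p = 0.621; 0.0887 to 0.347), the G2/M list had a higher median, and MYC had −0.07 ± 0.154 (adjusted p = 0.934; −0.306 to 0.0582). MDM2 had −0.03, MDM4 −0.17 and CDKN1A −0.03. Of 18675 genes tested, 65 were higher and 11 lower, and 68 of the 76 were over background. The count was 14 without shallow AOIs, 6 without D3, 14 without D5, 21 without V3, 49 without V5, 119 without V1 and 200 without D4, and the MHC genes named no longer passed without D3, D5 or V3, except TAP1 (adjusted p = 0.00399 without V3), nor did HLA-B without V5 (0.0504). The median of all genes moved from −0.01 to −0.10 with upper quartile scaling and to −0.11 with TMM factors from genes over background.

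Ki67+MYC- cells of D3 and V5 had less RNA of IGFBP7, a secreted protein, SPARC and CAV1 than Ki67+MYC+ cells of the same tumours. IGFBP7 was 16.1 ± 5.58 CPM against 39.7 ± 14.3 (n = 2 tumours; −1.28 ± 0.22, or ± 0.37 from own spread, edgeR adjusted p = 5.62e-05), SPARC 49.4 ± 26.1 against 96.3 ± 48.6 (−0.94, adjusted p = 0.0204), and CAV1, the caveolae protein, 14.0 ± 5.39 against 29.4 ± 0.28 (−1.07, adjusted p = 0.0166). SPARC was the 1 member of the fibroblast and matrix list that passed (3 lower adjusted over the list alone; median 0.01, camera adjusted p = 0.869), and 2 heat shock genes and 1 apoptosis regulator were lower adjusted over the list alone. MTRNR2L10, a humanin-like gene, was 245.6 ± 34.1 against 569.9 ± 226 CPM (−1.13), and TAGLN3 had −1.07. OTOF (−1.58) was not over background, and EML6 (−1.75) and TNR (1.71) each had 1 AOI far above all others. Ribosomal proteins (−0.19, 77 of 78 negative, camera adjusted p = 2.89e-13), germinal center genes (−0.19, 0.0445), translation factors (−0.13, 0.0241), MYC mRNA-binding proteins (−0.13, 0.0445), ribosome biogenesis (−0.12, 0.00726) and apoptosis regulators (−0.12, 0.0121) had lower medians and cholesterol synthesis a higher median (0.07, 0.0445), each with adjusted p = 0.968 with an estimated correlation. Among genes over background, whose median was −0.08 against 0.14 for the others, only ribosomal proteins and cholesterol synthesis of these 7 lists passed, and without D3 ribosome biogenesis (0.926) and translation factors (0.618) turned. Without AOIs of high background 5 of the 7 had another direction and translation factors passed as higher. The negative probe share of the Ki67+MYC- library was 15.4% against 10.5% in D3 and 10.98% against 12.2% in V5. MYC (−0.29 ± 0.206) and MKI67 (0.07) had edgeR adjusted p = 0.999 each. Of 18675 genes tested, 1 was higher and 7 were lower. With upper quartile scaling 0 were higher and 2 lower, and none passed with DESeq2 (192 at an unadjusted p under 0.05, against 615 in edgeR), among genes over background only (294) or without D3 (378 in edgeR). The count was 4 without V3, and the own spread was 2.02 to 10.7 times the shared spread.

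The interferon response list also had a higher median in Ki67-MYC- than in Ki67-MYC+ cells of D5 and V3, with 3 of 28 genes past the threshold. IFI6 was 535.8 ± 127 CPM against 257.3 ± 109 (n = 2 tumours; 1.04 ± 0.175, or ± 0.464 from own spread, edgeR adjusted p = 1.81e-05), IFITM1 263.4 ± 129 against 132.6 ± 44.3 (1.03, adjusted p = 3.61e-05) and IFI27 577.3 ± 4.85 against 324.5 ± 106 (1.01, adjusted p = 2.19e-05). These 3 of 28 interferon genes passed (7 adjusted over the list alone; median 0.34, camera adjusted p = 6.27e-06). MHC class II (0.30, adjusted p = 0.000195; 1 higher adjusted over the list alone), MHC class I (0.30, 0.00263; 1 higher adjusted over the list alone) and G2/M (0.05, 0.000913) had higher medians and ribosomal proteins a lower median (−0.17, 78 of 78 negative, 6.54e-05), with adjusted p = 0.995 with an estimated correlation for all 5 lists. Without D5 only MHC class II and ribosomal proteins of these 5 passed, while the interferon response (adjusted p = 0.172) and MHC class I (0.0594) did not and G2/M turned to lower (0.805). Adjusted over the list alone, 3 NF-kB targets were higher, and 1 stress response gene and 1 heat shock gene lower. The chemokine copies CCL4L2 (0.99) and CCL3L3 (0.83) and the caspase CASP10 (1.23) were higher in 1 of 2 tumours. TNR (3.15) and SLC27A1 (−2.11) each had 1 AOI far above all others, and BARX2 (−1.38) was not over background. MYC had −0.39 ± 0.181 (adjusted p = 0.999). Of 18675 genes tested, 7 were higher and 2 lower, with 7 higher and 0 lower under upper quartile scaling and 11 higher and 0 lower with TMM factors from genes over background. None passed with DESeq2 (419 at an unadjusted p under 0.05, against 715 in edgeR), the robust test (726) or only the tumours and segments compared (430), the count was 5 without D5, 22 without V1, 6 without D2, 6 without D3 and 14 without D4, and the own spread was 3.39 to 10.7 times the shared spread.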

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

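The tests of background, of the ribosome biogenesis list, of single tumours, of macrophage markers and of sample D2 were chosen after the results were seen, and the counts over other splits of the samples were planned.

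In Ki67+MYC+ cells, genes of growth and protein synthesis had lower medians with milademetan while genes at background had higher ones, a difference of −0.376 between genes over background and the others. A candidate explanation is the high negative probe share of the D4 and D5 libraries: the difference was 0.226 without them, −0.0624 with the share as a covariate, and −0.0548 (without D4) to −0.645 (without V1) with each tumour left out. A lower expression of MYC-induced genes in all milademetan tumours was neither shown nor excluded. The level of the ribosome biogenesis list relative to the 10 tumours was −0.622 in D4 and −0.418 in D5. It was 0.169 ± 0.0771 in D1, D2 and D3 and 0.109 ± 0.128 in vehicle tumours. The list's median log2 fold change was 0.0811 without D4 and D5 against −0.278 with them. Without D4 and D5, slides S1 and S3 hold vehicle only, and D2 lay near the vehicle tumours. On S2 the share was 10.5% in D3 and 12.18% in V5. On S4 it was 7.64% in D1, 9.09% in D2 and 10.11% in V1. Background there was lower with milademetan, the direction that raises expressed genes, so the value without D4 and D5 cannot decide. The list's median stayed lower with the covariate (−0.1) and with any 1 tumour left out (−0.082 to −0.419). Chance was not excluded for the 25 genes past the threshold: 18 of 100 splits of the 10 tumours, the real split included, gave as many. The highest other split gave 2025 (D1, D4, D5, V1 and V5 against the rest), and what set its sides apart was not tested. An effect of milademetan in the D4 and D5 tumours themselves was not tested and stays open. Background varied between the AOIs of these tumours, as from 8.0% to 39.4% in Ki67+MYC+ AOIs of D4. Without AOIs of a share over 20%, 14 of the 26 lists had the opposite direction, 2 of them passing in camera, and 2 passed in the same direction.

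Interferon and antigen presentation genes were higher in Ki67-MYC- than in Ki67+MYC+ cells. A difference in background is argued against, since the 46 genes of the 3 lists over background had a median 0.425 above that of all genes, with quartiles of 0.244 and 0.51. 1 tumour alone is argued against as well, since the lowest value with any tumour left out was 0.364 (without D5). Macrophages were neither shown nor excluded, and could not be, since those of the host are mouse cells and the panel targets human RNA. The 14 markers had a median log2 ratio of −0.228, only 3 were over background, and these went both ways (CD68 0.317, C1QB −0.358, FCER1G 0.455). A difference between the cell states by which the segments were chosen stays open as a hypothesis that the RNA of the stained proteins did not support (MKI67 0.27 and MYC −0.07, neither past the threshold), and the real split gave 65 genes past the threshold in the 4 tumours with both segments against at most 23 in other splits, where 8 splits (1 as large) are too few for a share under 0.05.

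Tumour D2 lay nearer the vehicle tumours for the genes that differed with milademetan in Ki67+MYC+ cells, at 15 of 15. A swap with a vehicle tumour was left open, since V5 lay nearer the milademetan tumours for 7 of 15 genes and the other vehicle tumours for 1 to 4. Splits with D2 exchanged for V5, V1, V4, V3 or V2 gave 1347, 277, 37, 31 and 30 genes past the threshold in edgeR. The labels as given had 25. These numbers do not settle a swap, since another split gave 2025 (D1, D4, D5, V1 and V5 against the rest). A few unusual AOIs of 1 segment are argued against, since the Ki67-MYC+ segment of D2 also lay nearer the vehicle tumours for 13 of 15. A wrong label or missed dosing of D2 alone and a tumour that did not respond cannot be told apart, since both predict the 15 of 15. The genes were picked by their difference between treatments, so the counts of nearer genes describe D2 and do not test the treatment.

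For the other comparisons between segments the splits were too few for a share under 0.05. Between Ki67-MYC+ and Ki67+MYC+ cells the real split of the 5 tumours gave 35 genes and the highest of the others 36 (2 of 16 as large), and between Ki67-MYC- and Ki67-MYC+ cells the 2 splits gave 0 and 1 (2 of 2 as large; edgeR with these libraries only, 430 genes at an unadjusted p under 0.05, and 0 with DESeq2 on all libraries).

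Among 103 groups of 4 or 5 samples, 11 had a sample far from the others. In simulated groups of independent normal values chance gave 5.02% of groups of 4 and 4.97% of groups of 5, about 1 in 20, but the groups here share tumours and most were picked as genes past the threshold, so this share is no test of the 11. MYC in Ki67+MYC+ cells was 223 CPM in V5, with the nearest vehicle tumour at 307. OTOF was 52.6 CPM in D3, with the nearest milademetan tumour at 15.6. IL1R2 was 60.2 CPM in D2, with the nearest milademetan tumour at 26.5. MPEG1 was 117 CPM in D2, with the nearest milademetan tumour at 58.9. The log2 ratio of Ki67-MYC+ to Ki67+MYC+ cells for MKI67 was 0.793 in D4, with the nearest tumour at 0.0198. Of the log2 ratios of Ki67-MYC- to Ki67+MYC+ cells, MDM4 had 0.0388 in V1 (nearest −0.292), EML6 −2.94 in D3 (nearest −0.543), RASIP1 −0.338 in D5 (nearest −1.33), PTBP1 −1.41 in D5 (nearest −0.295), PDIA6 1.1 in D5 (nearest 0.412) and IFI27 −0.101 in V1 (nearest 1.8).

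The treatment effect differed between Ki67-MYC+ and Ki67+MYC+ cells, by the interaction test of edgeR, for CFB (log2 difference −1.58), BARX2 (−1.87) and FAM9C (3.12). The test had 3 milademetan and 2 vehicle tumours. BARX2 and FAM9C were not over background, and no gene passed with DESeq2. Own spread of the 3 genes was 3.58 to 5.29 times the shared spread, so the difference is not established.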

How the results depend on the processing

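The robust test, the table with 0 as 1, TMM from genes over background, the settings without AOIs of high background, without genes resting on 1 AOI, without D4 and D5 and with the negative probe share as a covariate, and the list and depth settings added to the plan were chosen after the data were seen. Settings with regions as blocks took regions of 1 tumour as separate replicates, so their counts do not rest on animals.

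In Ki67+MYC+ cells the 25 genes past the threshold between treatments became 10 with RLE, 9 without shallow AOIs, 4 without a slide term, 137 (15 higher, 122 lower) with AOIs as libraries, 171 (29 and 142) with all segments, 8 without AOIs of high background, 9, 103, 9 and 115 without slide S1, S2, S3 and S4, and 0 with DESeq2, genes over background, the covariate, or without D4 and D5 (1192, 1004, 1229 and 1190 at an unadjusted p under 0.05); with 1 tumour left out they ranged from 8 to 205. In Ki67-MYC+ cells the 5 became 10 with RLE, 53 (35 higher, 18 lower) with a slide term, 22 with 0 as 1, 10 with the robust test, and 0 with upper quartile, genes over background, DESeq2, no shallow AOIs, limma voom of all libraries, TMM from genes over background or no AOIs of high background, with 161 (DESeq2) to 1330 (voom) at an unadjusted p under 0.05; with 1 tumour left out 0 to 41. In Ki67-MYC- cells the 96 became 59 with upper quartile, 29 with no filter, 15 with DESeq2 and 6 with voom of all libraries; with 1 tumour left out 14 to 149. For the interaction the 3 became 6 with upper quartile, 1 with genes over background, 9 with TMM from genes over background, 21 without AOIs of high background, and 0 with DESeq2, no shallow AOIs or voom (50, 145 and 451 at an unadjusted p under 0.05); with 1 tumour left out 1 to 16.

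For Ki67-MYC+ against Ki67+MYC+ cells the 25 became 60 with upper quartile, 48 with genes over background, 76 with TMM from them, 4 without shallow AOIs, 4 (3 higher, 1 lower) without AOIs of high background, 79 (51 and 28) with regions as blocks, and 0 with DESeq2 (1874 at an unadjusted p under 0.05); with 1 tumour left out 5 to 70. For Ki67-MYC- against Ki67+MYC+ cells the 76 became 14 without shallow AOIs; with 1 tumour left out 6 to 200. For Ki67+MYC- against Ki67+MYC+ cells the 8 became 2 with upper quartile, 2 with TMM from genes over background, 5 without shallow AOIs, 27 with regions as blocks, 14 without AOIs of high background, and 0 with genes over background or DESeq2 (294 and 192 at an unadjusted p under 0.05); with 1 tumour left out 0 to 8. For Ki67-MYC- against Ki67-MYC+ cells the 9 became 1 with genes over background, 1 with regions as blocks, 16 without AOIs of high background, and 0 with DESeq2, the robust test or only the segments compared (419, 726 and 430 at an unadjusted p under 0.05); with 1 tumour left out 5 to 22.

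Without the tumour as a replicate block, the segment comparisons gave 0, 1, 1 and 1 genes in this order (416 at an unadjusted p under 0.05 where edgeR gave 0). Tumour numbers do not pair animals: correlations of like-numbered tumours were 0.0886, 0.0482, 0.0586, −0.335 and 0.376, and 2 of 10 correlated best with their own number. With the number as a replicate block the treatment test in Ki67+MYC+ cells gave 18 genes (9 higher, 9 lower), 16 of them among the 25. This block was not run in Ki67-MYC+ cells, where 1 number was shared.

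Of the lists past the threshold between treatments, in Ki67+MYC+, Ki67-MYC+ and Ki67-MYC- cells and for the interaction, 26, 10, 4 and 0 became 0, 0, 0 and 0 with an estimated correlation (2, 0, 0 and 0 at an unadjusted p under 0.05). With fry 0, 0, 1 and 0 passed, the 1 not among the 4. With genes over background 14 (13 of the 26), 12 (all 10), 2 (among the 4) and 3 (all new) passed. Without D4 and D5, 10 passed: 2 of the 26 in the same direction, 6 of them in the opposite direction and 2 others; 19 of the 26 had the opposite direction, passing or not. Without AOIs of high background 6 passed, 2 of the 26 in the same direction, 2 in the opposite direction (14 had it, passing or not) and 2 others, and the interaction had 2 with upper quartile and 10 without AOIs of high background. In Ki67-MYC+ cells 9 passed without AOIs of high background, 8 of the 10 in the same direction and 1 other. With 1 tumour left out the counts of the 4 tests ranged from 6 to 27, 4 to 12, 3 to 9 and 0 to 12. Between segments, in the order above, 19, 18, 7 and 5 lists became 0 each with an estimated correlation (0, 2, 0 and 0 at an unadjusted p under 0.05) and with fry. The 19 were 12 with genes over background, 8 without AOIs of high background and 10 to 22 with 1 tumour left out, and instead of the 7, 11 passed without AOIs of high background (1 of the 7 in the same direction, 1 in the opposite; 5 of the 7 had the opposite direction, passing or not) and 1 to 12 with 1 tumour left out. Without D5, 2 of the 5 passed in the same direction.

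Of the values of named genes past the threshold across alternatives, 279 of 478 stayed past it in Ki67+MYC+ cells and none reversed. The figures were 37 of 89 in Ki67-MYC+ cells, 413 of 588 in Ki67-MYC- cells, 29 of 49 for the interaction, and 183 of 262, 602 of 807, 129 of 186 and 135 of 207 for the segment comparisons in the order above. With 1 tumour left out, 3 genes reversed: BARX2 between treatments in Ki67-MYC+ cells (log2 −2.06 to 0.00429), ACTA1 in Ki67-MYC- cells (−2.7 to 0.352) and OTOF in Ki67+MYC- against Ki67+MYC+ cells (−2.46 to 0.7). The cause of these changes was not tested, except where fewer tumours or genes entered. The tests of depth and negative probe share kept their side in every setting run, with the negative probe share p from 0.0952 to 0.659 with 1 tumour left out. The negative probes limit what low counts can show, as 9103 of the genes tested in Ki67+MYC+ cells were not over background.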

Other observations

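The genes singled out here were chosen after their values were seen, and no test was made of them.

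Interferon response varied widely between tumours within the Ki67+MYC+ cells of both treatments. IFI27, an interferon-induced mitochondrial protein, ranged from 33.2 CPM in V2 to 610 in D2, with 459 in D1 and 315 in V4. IFI6, which limits apoptosis and virus replication, ranged from 62.5 CPM in V2 to 735 in D2, with 463 in D1 and 414 in V4. IFITM1 ranged from 26.7 CPM in V2 to 259 in D2, with 247 in D1, and IFI44L from 54.7 in V2 to 312 in D2. D2 was also the milademetan tumour whose levels of BMP7, SPRR2A, IL1R2 and CCL22 lay nearest the vehicle tumours.

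Some genes had a high count in 1 AOI only. EML6, a microtubule-associated protein, reached 988 CPM in 1 AOI of D3, with 52.1 in the next highest AOI. SLC27A1, a fatty acid transporter, reached 1699 CPM with 66.8 next, TNS1 1512 with 79.2 next, and PTPRT 1458 with 71.6 next. Altogether 23 genes had such an AOI.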
